A study of Homo sapiens with 9 samples.

How the data were processed

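RNA was extracted with TRIzol, purified with poly(A) selection and made into libraries with a directional NEBNext Ultra kit, per the labels' protocols, and sequenced on an Illumina HiSeq, per the series' design text. The libraries come from cells labelled NB4 after 48 h with DMSO, FB23 or FB23-2, with 3 libraries per group. The deposited files hold 1 table per library with 26830 genes. The expected count column gives reads per gene as estimated by RSEM, per the file headers, and the submitters' processing notes name RSEM 1.2.31 and the genome build GRCh38. The TPM column gives transcript abundance by RSEM, scaled for gene length and library total, per the file headers, and the FPKM column gives fragments by RSEM per kilobase of gene, scaled to the library total, per the file headers. Each deposited file also gives the length and effective length of the genes in bases, per the file headers. The aligner, the annotation release, the strand setting and any filters are not given in the sources used here.

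Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13365. Libraries were scaled with TMM factors, and a quasi-likelihood model with 1 mean per group was fitted to all 9 libraries, so that the groups shared 1 estimate of the spread. The common biological coefficient of variation was 5.12%. Each comparison (FB23 against DMSO, FB23-2 against DMSO and FB23-2 against FB23) was tested with the quasi-likelihood F test, two-sided, and p-values were adjusted over all tested genes by Benjamini and Hochberg. Genes with an adjusted p under 0.05 are called. Standard errors of log2 fold changes come from the F statistic, and intervals are 95% intervals. CPM values use the TMM scaling. Fold changes of genes with few counts depend on the prior count of 0.125. TPM was used as deposited for the levels of marker genes and FPKM was not used here.

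A total of 26 gene lists were fixed, of which 24 had at least 3 tested members. They were compared with all other genes by limma 3.58.1 camera with a preset correlation of 0.01, again with an estimated correlation, and by fry as a self-contained alternative, with adjustment over the 24 lists. Counts of called members are given from the adjustment over all genes and adjusted over the list alone. The named genes followed a rule: in each comparison the 8 with the largest rise and the 8 with the largest fall among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, the 2 highest and 2 lowest called members of each list, and always FTO, ASB2, RARA, MYC and CEBPA. The samples, the fit, the lists, the rule for named genes and the first set of other ways of processing were chosen before the data were examined. Genes with a clone-like name were skipped, and the text describes some, not all, of the genes that met the rule.

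Also fixed in advance were fits with DESeq2 size factors and upper-quartile factors in edgeR, no filter on low counts, a filter of 1 CPM in at least 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, fits of only the 6 libraries compared, the replicate number as a block, an added minimum of 1 on the absolute log2 fold change, and leaving out each library in turn. After the data were seen, scaling by library totals, thinning of all libraries to the smallest total and removal of trends on GC content and length were added. GC content was known for 94.3% of tested genes. Coordinates and GC content are from GENCODE release 29 on GRCh38.

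Totals ran from 12360291 to 38410750 expected counts, and genes with at least 1 count from 15102 to 16742 per library. A gene with 0 counts is given an upper limit of 3 counts over the libraries named. Limits and counting intervals cover counting error only, because reads without molecular identifiers are not independent molecules. The median fragment length was 399 bases in FB23 replicate 1 and 367 to 379 in the others, from the difference between length and effective length. The 10 most abundant genes took 5.54% to 5.83% of counts with DMSO and FB23 and 6.95% to 7.32% with FB23-2, and TMM factors were 0.954 to 0.988 and 1.05 to 1.08. The first principal component held 87.5% of the variance and set the FB23-2 libraries apart from the others. No pair of replicates was identical.

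The fit was tested on simulated data with 12641 tested genes. In it 200 genes were changed and another 30 were shifted as a list. Genes were drawn independently, and each change with FB23-2 was set to 2 times that with FB23. For FB23 against DMSO it recovered 79.0% of genes changed by 0.5 on the log2 scale, 93.7% of those changed by 1 and 100% of those changed by 2, with 3.88% of calls false. For FB23-2 against DMSO it recovered 91.9% at 1 and 100% at 2 and at 4, with 3.17% of calls false. A simulated slope of 2 between the compounds came out as 1.99, and 0 of 20 unshifted lists had a camera p under 0.05. The data held far more changed genes, changes with FB23-2 alone and list members that vary together. These rates, the slope and the list result may therefore not carry over to the data.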

Results

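Polyadenylated RNA was sequenced from human cells labelled NB4 after 48 h with the solvent DMSO, with FB23 or with FB23-2, in 3 libraries per group and 9 libraries in all. NB4 is a line derived from an acute promyelocytic leukaemia, and the labels give its cell type as acute monocytic leukaemia. The series title names inhibition of FTO, an enzyme that removes methyl groups from N6-methyladenosine (m6A) in RNA, as the purpose of both compounds. Doses are not in the labels, so the compounds were compared at the same time only. Expected counts summed to 17195555, 18514243 and 16804604 in DMSO replicates 1 to 3, 12360291, 31326915 and 38410750 with FB23, and 24595521, 18247576 and 15207132 with FB23-2. Of the 26830 genes in the files, 13365 had enough counts to be tested and 7863 had no count in any library. The labels do not say whether the replicates came from separate cultures, so the p-values may measure technical spread between libraries of 1 culture.

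Globin transcripts were among the most abundant in the DMSO libraries, whereas the granule genes of promyelocytes were at or near 0. In DMSO, HBG2, a fetal globin gene, stood at 8103 ± 259 TPM (SD, n = 3), HBZ, an embryonic globin gene, at 7165 ± 349 TPM and HBA1 at 4842 ± 177 TPM, while the adult gene HBB stood at 2.95 ± 1.05 TPM. KLF1, a transcription factor of red cell precursors, was at 286 TPM. MPO and CTSG, which encode granule proteins of promyelocytes, had 0 counts over the 9 libraries, which allows up to 0.0156 CPM (counts scaled to a common library total), and ELANE had 1 count. PRTN3 and AZU1, also granule genes, reached at most 0.76 and 1.77 TPM in any library. CD33, a surface marker of the myeloid lineage, was measured at 44.0 TPM in DMSO, 38.8 TPM with FB23 and 44.4 TPM with FB23-2. These levels hold for the DMSO libraries of every comparison that follows. The cells are called by their label, NB4.

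**Figure D1:**
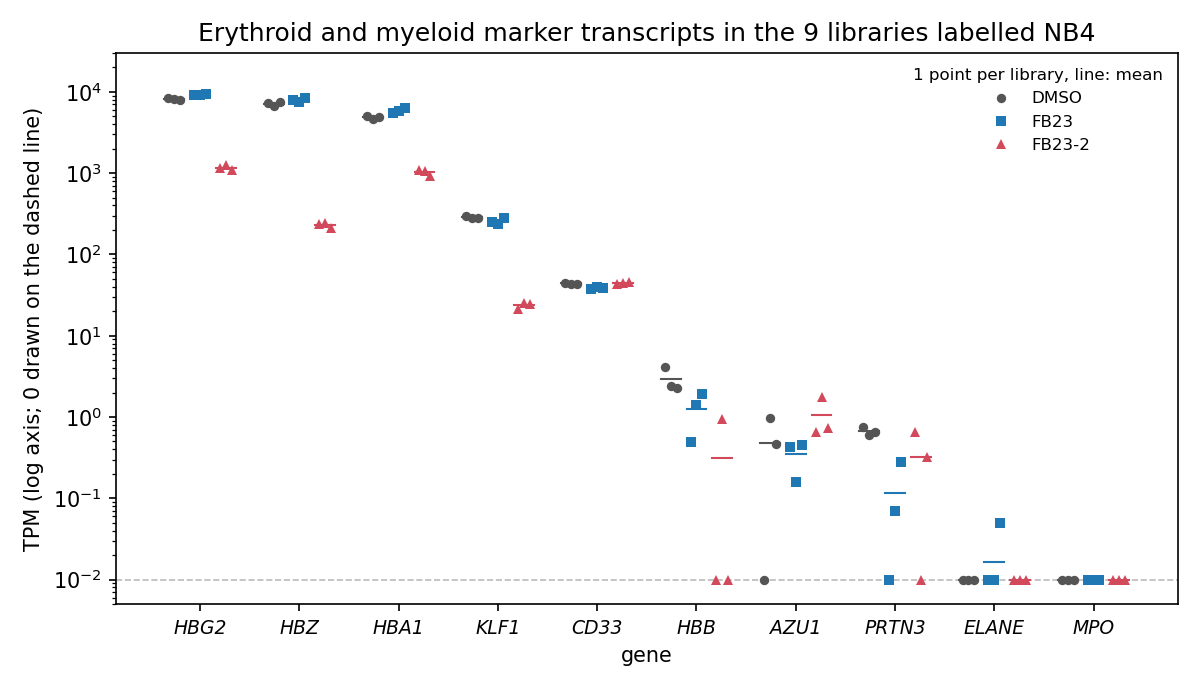
TPM on a log axis of 10 erythroid and myeloid marker genes in each library, with 1 point per library, the mean of each group as a line and values of 0 on the dashed line. The globin genes HBG2, HBZ and HBA1 lie between 4673 and 9462 TPM in the DMSO and FB23 libraries and lower with FB23-2, and MPO is at 0 in all 9 libraries.

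FTO and the transcripts that the leukaemia literature ties to it were read first. FTO itself (chromosome 16, 53701692 to 54158512, GRCh38) was measured at 39.8 ± 2.01 CPM (SD, n = 3) in DMSO, 37.1 ± 0.966 with FB23 and 31.3 ± 1.52 with FB23-2. Its log2 fold change was -0.10 ± 0.06 (SE) with FB23, which did not pass the test (edgeR, adjusted p = 0.253), and it fell by 0.35 ± 0.06 with FB23-2 (adjusted p = 7.33e-05). In TPM as deposited the means were closer, at 13.4 in DMSO, 12.7 with FB23 and 12.6 with FB23-2. On that scale the FB23-2 libraries (11.8 to 13.07 TPM) overlapped those of DMSO (12.8 to 14.08 TPM). The size of the FTO fall with FB23-2 therefore depends on the scale used. MYC, a transcription factor of growth genes (chromosome 8, 127735434 to 127741434), fell by 0.30 ± 0.05 with FB23 and by 1.83 ± 0.05 with FB23-2, from 1027 CPM in DMSO to 833 and 289 CPM. RARA, a retinoic acid receptor gene, fell by 0.89 ± 0.09 with FB23-2 and by 0.32 ± 0.09 with FB23, and without FB23 replicate 2 the call with FB23 was lost (log2 fold change -0.30, edgeR adjusted p = 0.0585). CEBPA, a transcription factor of myeloid maturation, stood at log2 0.25 ± 0.10 with FB23, which did not pass (adjusted p = 0.082), and rose by 0.35 ± 0.10 with FB23-2 (adjusted p = 0.0046). That rise was lost when trends on GC content and length were removed (log2 fold change 0.03, edgeR adjusted p = 0.813, and between 0.00014 and 0.813 over its alternatives). ASB2, a ubiquitin ligase subunit induced by retinoic acid, had 0 counts in DMSO and FB23 and 11 counts over the FB23-2 libraries, too few to be tested. As a list, the 3 tested genes MYC, RARA and CEBPA did not differ from other genes with FB23 (camera, adjusted p = 0.204) or FB23-2 (0.139). Camera looks for a shift in 1 direction, and these genes had fold changes in both. It therefore cannot tell whether they responded. By fry, which tests against no change, the list was called as lower with FB23-2 (adjusted p = 2.08e-06) but not with FB23 (0.0698). With FB23, 2 of the 3 genes were lower when adjusted over all genes, and 2 were lower and 1 higher when adjusted over the list alone. With FB23-2, 1 was higher and 2 lower in both ways.

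**Figure D2:**
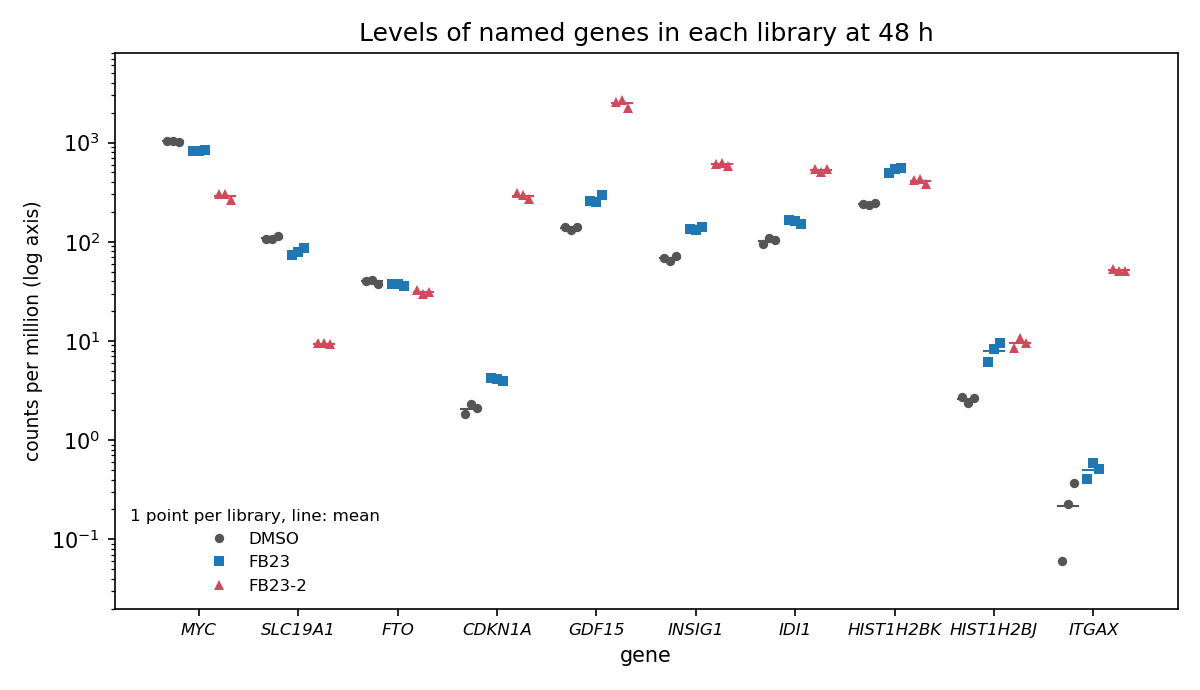
CPM on a log axis of 10 named genes in each library, with 1 point per library and the mean of each group as a line. MYC falls from 1027 CPM in DMSO to 289 CPM with FB23-2, and CDKN1A rises from 2.08 to 291 CPM.

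With FB23 against DMSO, the question was which transcripts the compound alone shifted. Histone genes, cholesterol synthesis genes and p53 targets were higher, and ribosome biogenesis genes were lower. HIST1H2BK, a core histone gene, rose 2.20-fold (log2 1.14 ± 0.05 SE, 3 libraries per group), from 240 ± 3.10 to 528 ± 36.5 CPM (SD). INSIG1, which holds back the sterol-sensing machinery in the endoplasmic reticulum, rose 1.98-fold (log2 0.98 ± 0.05). CDKN1A, the cell cycle inhibitor p21, rose 1.96-fold (log2 0.97 ± 0.14), and GDF15, a secreted stress factor, 1.95-fold (log2 0.97 ± 0.07). In all, 3144 genes were called (23.5% of those tested, edgeR at an adjusted p under 0.05), 1647 higher and 1497 lower (1881 and 1172 with library totals, 1955 and 2568 with GC and length trends removed), with a median absolute log2 fold change of 0.29, and 155 of them changed by at least 1 on the log2 scale, 102 up and 53 down. All 3 FB23 libraries lay beyond all 3 DMSO libraries for 37.9% of genes, where chance gives 10%.

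Among genes with a mean log2 CPM of at least 1 and no overlap between the groups, the largest rises included those of ARC, an immediate-early gene of synaptic plasticity, by log2 2.55 ± 0.49, CAPN5, a calpain protease, by 1.90 ± 0.23, and the histone genes HIST1H2BJ and HIST1H3D, by 1.68 ± 0.17 and 1.63 ± 0.20. RN7SL2, an RNA of the signal recognition particle that carries no poly(A) tail, rose by 1.75 ± 0.28. It shares reads with a near-identical copy, RN7SL1, which was not called (0.15 ± 0.40, edgeR adjusted p = 0.833). GOLGA8O had 4 counts in DMSO and 55 with FB23 (log2 3.01 ± 0.50), and belongs to a family of close paralogs among which reads may be split. Calls for 2 others hung on single libraries: EFR3B (log2 2.37) was lost without DMSO replicate 3 (1.84, edgeR adjusted p = 0.0786) or FB23 replicate 2 (2.08, adjusted p = 0.0738), and ATP10D (1.47) without DMSO replicate 2 (1.31, adjusted p = 0.0724) or FB23 replicate 2 (1.37, adjusted p = 0.0545). Within the same limits, the largest falls were those of SLFN14, a ribonuclease of the Schlafen family, by 1.47 ± 0.19, FYB, an adaptor protein of T cells and platelets, by 1.43 ± 0.17, PLEKHA7, a cell junction protein, by 1.39 ± 0.13, and PRG2, an eosinophil granule protein, by 1.37 ± 0.12. FAM178B, SELPLG (a ligand of P-selectin), SCGN (a calcium-binding protein) and SLC6A19 (an amino acid transporter) fell by between 1.27 and 1.36.

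Ribosome biogenesis targets of MYC fell together with FB23: 28 of 34 were lower, 0 higher and 6 not called, and 32 were lower when adjusted over the list alone (median log2 fold change -0.25, camera adjusted p = 3.48e-19). SLC19A1, a folate transporter, fell by 0.45 ± 0.06 and MYBBP1A, a nucleolar protein, by 0.43 ± 0.05. Replication-dependent histone genes, whose transcripts usually lack a poly(A) tail, had 13 of 16 higher and 0 lower (14 higher over the list alone, median 1.13, adjusted p = 4.05e-16). Cholesterol synthesis and SREBP targets had 16 of 28 higher and 1 lower (20 and 2 over the list alone, median 0.22, adjusted p = 3.21e-10), with IDI1, an isoprenoid enzyme, up by 0.63 ± 0.06. Of 23 p53 targets 8 rose and 1 fell (14 and 2 over the list alone, adjusted p = 0.000228), CDKN1A and GDF15 among the former and AEN, a nuclease of apoptosis, down by 0.42 ± 0.05. The list of genes often raised by histone deacetylase inhibitors had 9 of 12 higher and 0 lower in both ways of adjusting (median 0.47, adjusted p = 1.60e-12), led by SYT11, a vesicle protein, at 1.31 ± 0.24 and by HIST1H2BK. It shares CDKN1A with the p53 list, so it is not independent of that list. It also holds the histone gene HIST1H2BK, which is not a member of the replication-dependent histone list. Those 5 lists passed with an estimated correlation too, at adjusted p between 0.0102 and 0.0282.

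NRF2 targets had 9 of 17 members higher and 2 lower with FB23, in both ways of adjusting (median 0.17, camera adjusted p = 1.61e-05). That call was lost with an estimated correlation (adjusted p = 0.224 with an estimated correlation). OSGIN1, an oxidative stress response gene, rose 2.29-fold, from 3.52 ± 0.393 to 7.95 ± 0.798 CPM (SD), and FTL, the ferritin light chain, rose by 0.67 ± 0.05. Cytosolic ribosomal proteins passed the preset test as lower (adjusted p = 0.0352, and adjusted p = 0.746 with an estimated correlation), with 1 of 39 lower and 0 over the list alone. Without DMSO replicate 1 that list no longer passed (adjusted p = 0.0879), nor without FB23 replicate 1 (adjusted p = 0.799), and the single call was RPL23, at -0.16, itself lost in 10 settings, among them upper-quartile factors (-0.16, edgeR adjusted p = 0.0558) and the replicate block (-0.16, adjusted p = 0.0804).

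The other lists were not called with FB23, and many held genes that moved in both directions. E2F targets of DNA replication had 7 of 38 higher and 7 lower (7 and 8 over the list alone, median -0.01, and 0.01 when scaled by library totals): RRM2, a subunit of ribonucleotide reductase, rose by 0.47 ± 0.04 and TK1 by 0.33 ± 0.06, while the helicase subunit MCM5 fell by 0.35 ± 0.05. Of 31 genes of mitosis 3 were higher and 6 lower (3 and 7 over the list alone), with the mitotic kinase PLK1 down by 0.32 ± 0.04. Myeloid maturation markers had 2 of 14 higher and 4 lower (2 and 5 over the list alone), with ITGAM, the integrin CD11b, down by 0.81 ± 0.11. In the list of promyelocyte granule and progenitor genes, 1 of 9 rose and 2 fell (2 and 3 over the list alone): SERPINB1, a protease inhibitor of myeloid cells, rose by 0.51 ± 0.05, and MYB, a progenitor transcription factor, fell by 0.45 ± 0.05. Its median was 0.08 but its mean -0.17, and its camera test pointed down. Integrated stress response targets had 6 of 25 higher and 5 lower (8 and 5 over the list alone), with ATF3, a stress-induced factor, up by 0.83 ± 0.10 and STC2, a secreted glycoprotein, down by 0.88 ± 0.17. Among 17 interferon-stimulated genes 4 rose and 4 fell (4 and 5 over the list alone), IFI6 by 0.87 ± 0.18 and IFIT1 by -1.46 ± 0.28. Glycolysis enzymes had 4 of 18 higher and 6 lower (4 and 8 over the list alone), with ALDOC up by 0.66 ± 0.08 and HK2 down by 0.42 ± 0.05, and hypoxia targets 5 of 21 higher and 4 lower (5 and 5 over the list alone).

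In the remaining lists few members passed with FB23. Apoptosis regulators had 4 of 21 higher and 1 lower in both ways of adjusting, with the survival gene MCL1 up by 0.23 ± 0.05 (list median 0.03, mean -0.02, camera direction up). NF-kB and inflammatory genes had 2 of 18 higher, among them NFKB2 by 0.32 ± 0.07, and 1 lower in both ways (median -0.02, mean 0.12, camera direction up). Erythroid and megakaryocyte markers had 3 of 13 higher and 1 lower (3 and 2 over the list alone, median -0.01, mean 0.03, camera direction up, and median 0.01 when scaled by library totals), with ALAS2, the first enzyme of haem synthesis in red cells, up by 0.51 ± 0.05. The m6A list had 0 of 21 higher and 4 lower in both ways, among them IGF2BP1, an m6A reader, by -0.19 ± 0.05. In the unfolded protein response list 2 of 18 were higher and 1 lower (1 and 1 over the list alone), EDEM1 by 0.29 ± 0.05. Oxidative phosphorylation subunits had 0 of 31 higher and 2 lower in both ways, SDHB and ATP5B, and both calls were lost without DMSO replicate 1 (edgeR adjusted p = 0.0617 and 0.0708), DMSO replicate 2 (0.0549 and 0.0679) or FB23 replicate 2 (0.0537 and 0.0721). Epithelial and fibroblast markers had 1 of 6 higher, KRT8 by 0.37 ± 0.06, and 2 lower, EPCAM by -0.46 ± 0.05 and KRT19 by -0.41 ± 0.07 (2 and 2 over the list alone). Aryl hydrocarbon receptor targets had 2 of 5 higher and 0 lower in both ways, with NQO1, a quinone reductase, up by 0.49 ± 0.06. That list missed the threshold (camera adjusted p = 0.0698) and passed without DMSO replicate 3 (adjusted p = 0.0431) or FB23 replicate 1 (adjusted p = 0.0463). Neither of the 2 lymphoid genes that could be tested was called, and the 13 mitochondrially encoded mRNAs were not analysed here.

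With FB23-2 against DMSO, the question was the same for the related compound, and the shifts were large: ribosome biogenesis genes were lower, while p21, cholesterol synthesis and hypoxia genes were higher. CDKN1A (chromosome 6, 36676460 to 36687339) rose 140-fold (log2 7.13 ± 0.09 SE, 3 libraries per group), from 2.08 ± 0.237 to 291 ± 18.5 CPM (SD). ITGAX, the integrin CD11c of monocytes and dendritic cells (chromosome 16, 31355134 to 31382997), rose by log2 7.85 ± 0.17, from 0.218 ± 0.155 to 51.6 ± 1.36 CPM. HBZ, the embryonic globin gene, fell by 5.16 ± 0.09, from 1154 ± 56.1 to 32.2 ± 2.92 CPM, and HEMGN, a nuclear protein of blood precursors, by 4.66 ± 0.07. A total of 11041 genes were called (82.6% of those tested, edgeR), 5523 higher and 5518 lower (6451 and 4642 with upper-quartile factors, 6294 and 4754 with library totals), with a median absolute log2 fold change of 0.89, and 4913 changed by at least 1 on the log2 scale, 2767 up and 2146 down. The groups did not overlap for 84.3% of genes, where chance gives 10%. Fold changes are relative to the TMM scaling: the median of all genes was shifted by 0.17 with upper-quartile factors and by 0.15 with library totals in this comparison, and by 0.17 and 0.13 between the compounds.

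Other genes with very large rises were L1CAM, a neural adhesion molecule, by log2 7.74 ± 0.30, FXYD6, a regulator of the sodium pump, by 7.35 ± 0.31, the cytokine receptor IL21R by 7.34 ± 0.19 and the peptidase inhibitor PI16 by 7.23 ± 0.20. CXCL8, the chemokine interleukin-8, had 2 counts in DMSO and 448 with FB23-2, a count ratio of 183 with a 95% counting interval of 50.4 to 1517. RGPD5 had 0 counts in DMSO and 1665 with FB23-2, at least 471-fold higher against 3 counts over the group. RGPD5 shares reads with paralogs, and RGPD8 went from 1747 counts to 310, so both values are uncertain. Large falls were seen for ACTL8, an actin-like gene, by log2 -5.74 ± 0.13, KCNQ5, a potassium channel, by -5.64 ± 0.15, TNFRSF8, the receptor CD30, by -5.27 ± 0.09, TRDN, a protein of calcium release, by -5.20 ± 0.39, and SOX21, a transcription factor, by -4.67 ± 0.30.

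All 34 ribosome biogenesis targets of MYC fell with FB23-2 (median log2 fold change -2.37, camera adjusted p = 1.63e-49). NOP16, a nucleolar protein, fell by 3.69 ± 0.09 and SLC19A1 by 3.53 ± 0.07. In the cholesterol list 26 of 28 were higher and 2 lower (median 1.70, adjusted p = 6.68e-24), with the mevalonate enzyme MVD up by 3.51 ± 0.07 and the sterol carrier STARD4 by 3.30 ± 0.07. Hypoxia and HIF targets had 18 of 21 higher and 3 lower (median 1.96, adjusted p = 4.51e-11). NDRG1, a stress-induced growth regulator, rose by 5.15 ± 0.07, and CA9, a carbonic anhydrase, went from 2 to 166 counts, a count ratio of 67.9 (95% counting interval 18.5 to 565). The p53 list had 18 of 23 higher and 3 lower (median 0.96, adjusted p = 2.47e-08), with TP53INP1, a p53 cofactor, up by 4.46 ± 0.11 and TRIAP1 down by 1.97 ± 0.07. Genes often raised by histone deacetylase inhibitors had 11 of 12 higher and 0 lower (median 2.22, adjusted p = 5.03e-13), with the chaperone CLU up by 5.96 ± 0.11. Every one of the 16 tested histone genes was higher (median 3.32, adjusted p = 8.75e-08, where 2 other RNAs without a poly(A) tail had a median of 1.47), HIST2H2BE by 4.88 ± 0.10 and HIST1H4H by 4.81 ± 0.37. Those 6 lists also passed with an estimated correlation, at adjusted p between 0.0023 and 0.0273. Adjusted over the list alone, the counts of all lists in this comparison were the same as over all genes.

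A further 10 lists passed the preset test with FB23-2 but not with an estimated correlation, whose adjusted p follows each count. Mitosis genes had 3 of 31 higher and 28 lower (adjusted p = 0.101 with an estimated correlation): PLK1 fell by 2.85 ± 0.05 and CDC20, an activator of the anaphase-promoting complex, by 2.82 ± 0.06, while the phosphatase CDC25C rose by 0.76 ± 0.09. Oxidative phosphorylation subunits had 0 of 31 higher and 30 lower (adjusted p = 0.187 with an estimated correlation), among them ATP5G1 by -2.80 ± 0.11. Erythroid and megakaryocyte markers had 3 of 13 higher and 10 lower (adjusted p = 0.0736 with an estimated correlation): KLF1 fell by 3.84 ± 0.08 and HBG2 by 3.01 ± 0.08, while the platelet integrin ITGB3 rose by 3.83 ± 0.31. Of 18 NF-kB and inflammatory genes 16 were higher and 1 lower (adjusted p = 0.0856 with an estimated correlation), TNFRSF9, a costimulatory receptor, by 7.03 ± 0.24. Apoptosis regulators had 16 of 21 higher and 4 lower (adjusted p = 0.0736 with an estimated correlation), with the inhibitor of apoptosis BIRC3 up by 3.92 ± 0.20, the death-promoting BMF up by 3.82 ± 0.09 and cytochrome c, CYCS, down by 1.58 ± 0.05. Myeloid maturation markers had 11 of 14 higher and 3 lower (adjusted p = 0.187 with an estimated correlation), with the lysosomal macrophage marker CD68 up by 2.49 ± 0.12 and ITGAM down by 0.54 ± 0.11. The m6A list had 1 of 21 higher, the demethylase ALKBH5 by 0.47 ± 0.05, and 18 lower, among them the methyltransferase METTL16 by -1.89 ± 0.07 (adjusted p = 0.253 with an estimated correlation). All 5 aryl hydrocarbon receptor targets were higher (adjusted p = 0.0736 with an estimated correlation), CYP1B1, a cytochrome P450 enzyme, by 3.20 ± 0.22. Epithelial and fibroblast markers had 5 of 6 higher, PDGFRB by 4.77 ± 0.35, and 1 lower, EPCAM by -1.77 ± 0.06 (adjusted p = 0.122 with an estimated correlation). Glycolysis enzymes had 10 of 18 higher, ALDOC by 3.82 ± 0.08, and 5 lower, LDHB by -1.42 ± 0.05 (adjusted p = 0.549 with an estimated correlation), and without DMSO replicate 3 they missed the threshold (adjusted p = 0.0519).

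Not called as lists with FB23-2 were E2F targets, with 8 of 38 higher and 25 lower (camera adjusted p = 0.0945), though E2F1 rose 2.01-fold, from 82.8 to 166 CPM, and MCM5 fell by 1.34 ± 0.05. Interferon-stimulated genes had 11 of 17 higher and 4 lower, IFI6 by 3.55 ± 0.15 and IFIT1 by -1.86 ± 0.30 (adjusted p = 0.0917). NRF2 targets had 9 of 17 higher and 6 lower, OSGIN1 by 2.52 ± 0.11 and the antioxidant gene SRXN1 by -1.22 ± 0.05. Integrated stress response targets had 8 of 25 higher and 13 lower, with ATF3 up by 3.68 ± 0.09 and STC2 down by 2.20 ± 0.20. That list's median was -0.15, its mean 0.05 and its camera direction up, and the median was 0.03 with upper-quartile factors. In the unfolded protein response list 5 of 18 were higher, EDEM1 by 2.00 ± 0.05, and 10 lower. Ribosomal proteins had 5 of 39 higher and 22 lower (median -0.16, and 0.02 with upper-quartile factors). Promyelocyte granule and progenitor genes had 4 of 9 higher, GFI1, a repressor of myeloid development, by 1.66 ± 0.19, and 4 lower, MYB by -1.80 ± 0.05 (median -0.02, mean 0.00, camera direction down, and median 0.15 with upper-quartile factors). The 2 lymphoid genes with enough counts, CD3D and ZAP70, rose by 2.38 ± 0.18 and 1.60 ± 0.46, and formed too small a list to test.

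**Figure D3:**
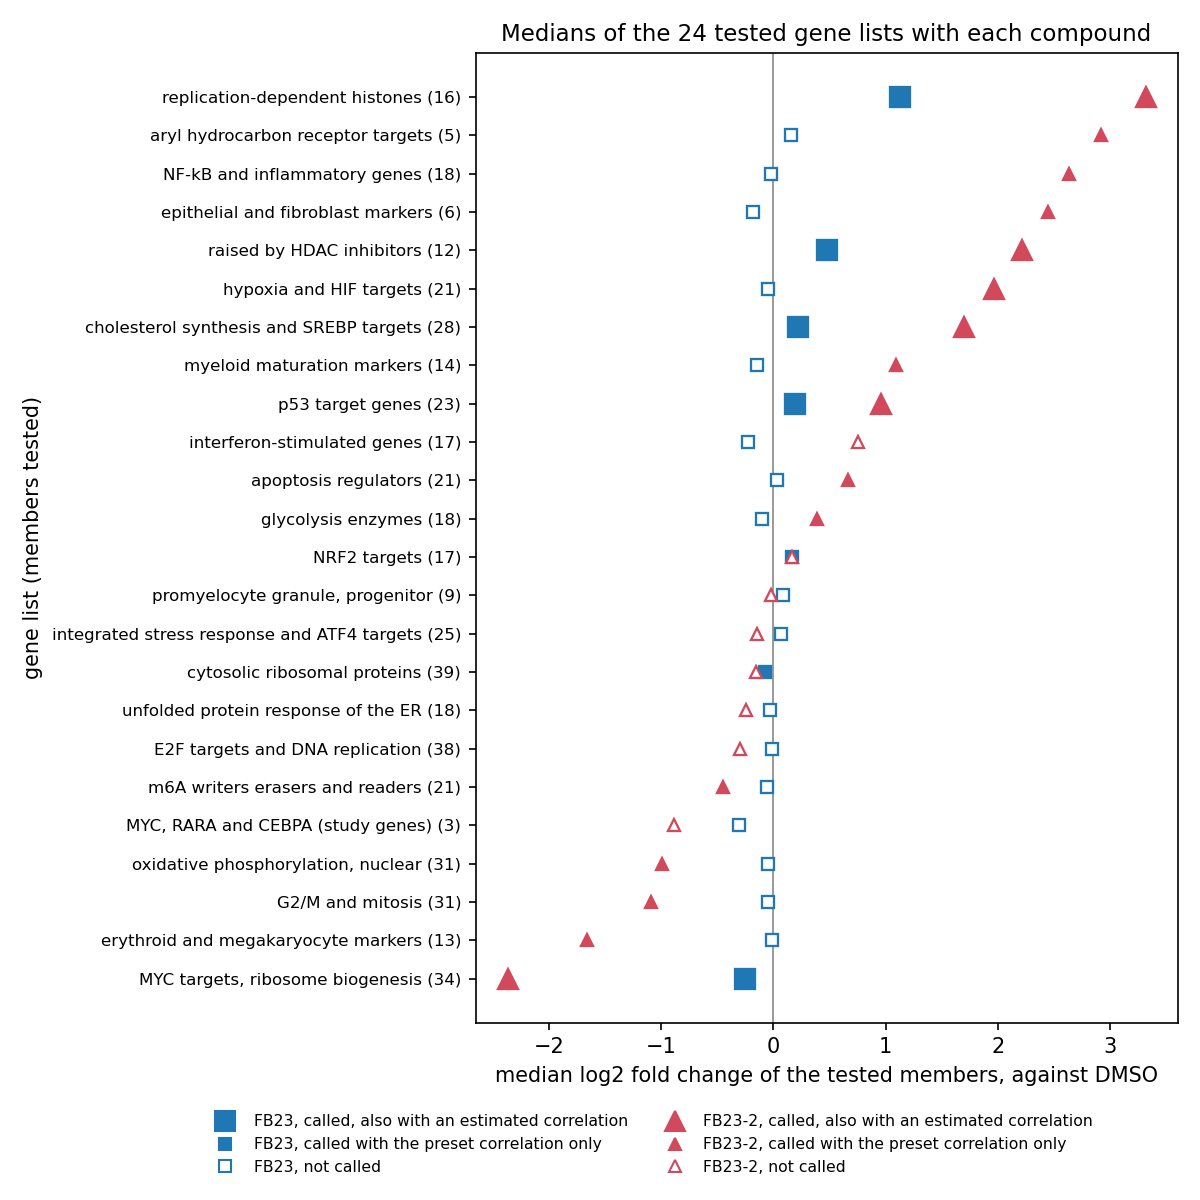
Median log2 fold change against DMSO of the tested members of each of 24 gene lists, with squares for FB23 and triangles for FB23-2 and filled symbols for lists called by camera. Medians with FB23-2 run from -2.37 for ribosome biogenesis targets of MYC to 3.32 for histone genes, and with FB23 from -0.30 for the study genes to 1.13 for histone genes.

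FB23-2 against FB23 tested how the compounds differed at the same time, with DMSO entering only through the filter, the scaling and the spread. CDKN1A was higher with FB23-2 than with FB23 by log2 6.16 ± 0.07 (SE, 3 libraries per group) and ITGAX by 6.60 ± 0.13. MYC was lower by -1.53 ± 0.05, HBZ by -5.28 ± 0.09 and TNFRSF8 by -4.43 ± 0.09. Of the tested genes 10890 were called (81.5%, edgeR), 5395 higher and 5495 lower with FB23-2 (6395 and 4552 with upper-quartile factors, 6140 and 4762 with library totals), and the groups did not overlap for 81.2%, where chance gives 10%. Conversely, the 95% interval of the difference lay within 0.5 of 0 on the log2 scale for 3435 genes, or 25.7%. FTO was lower with FB23-2 by -0.24 ± 0.06 (95% interval -0.38 to -0.11, edgeR adjusted p = 0.00165), a call that was lost with upper-quartile factors (log2 fold change -0.08, adjusted p = 0.255) and with library totals (-0.12, adjusted p = 0.093). For CEBPA no difference was detected (log2 0.10, 95% interval -0.11 to 0.30, adjusted p = 0.362), but it was called with upper-quartile factors (0.26, edgeR adjusted p = 0.0173) and with library totals (0.22, adjusted p = 0.0399). RARA was lower by -0.57 ± 0.09.

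Further genes that set FB23-2 apart upward were L1CAM at log2 7.27 ± 0.26, CXCL8 at 7.02 ± 0.34 with 4 counts in FB23, PPL, a protein of cell junctions, at 6.75 ± 0.11, FXYD6 at 6.59 ± 0.26 and PI16 at 6.50 ± 0.17. RGPD5 had 0 counts in FB23 and was at least 746-fold higher with FB23-2, with the same doubt over its paralogs. Downward were ACTL8 at -5.15 ± 0.13, TRDN at -5.10 ± 0.39, KCNQ5 at -5.05 ± 0.15, the amino acid transporter SLC38A5 at -4.11 ± 0.07 and USP2-AS1 at -4.19 ± 0.24, which lies antisense to USP2 and is uncertain because the counting is not stated to use strand. In the lists, 17 of 24 differed by camera. The 6 that passed with an estimated correlation were ribosome biogenesis targets (34 of 34 lower, median -2.14), cholesterol genes (26 higher and 2 lower of 28, median 1.53), hypoxia targets (18 and 1 of 21), p53 targets (18 and 4 of 23), genes often raised by histone deacetylase inhibitors (10 and 1 of 12) and histone genes (15 and 0 of 16, median 1.95). HIST1H2BK went the other way from most histone genes and was lower with FB23-2 than with FB23, at -0.36 ± 0.05. The interval of the difference for HIST1H2BJ ran from -0.08 to 0.50.

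The other 11 lists called between the compounds lost the call with an estimated correlation. Counted as higher and lower with FB23-2, they were interferon-stimulated genes (12 and 2 of 17, adjusted p = 0.255 with an estimated correlation), oxidative phosphorylation (0 and 31 of 31, adjusted p = 0.21 with an estimated correlation), the m6A list (1 and 19 of 21, adjusted p = 0.198 with an estimated correlation) and glycolysis (12 and 3 of 18, adjusted p = 0.402 with an estimated correlation). Apoptosis regulators (15 and 4 of 21) had adjusted p = 0.152 with an estimated correlation, myeloid markers (12 and 1 of 14) 0.101 and NF-kB genes (16 and 1 of 18) 0.101. Erythroid and megakaryocyte markers (3 and 9 of 13) had adjusted p = 0.0527 with an estimated correlation, mitosis genes (2 and 27 of 31) 0.0687, aryl hydrocarbon receptor targets (5 and 0 of 5) 0.0725 and epithelial and fibroblast markers (5 and 1 of 6) 0.0939. Not called between the compounds were E2F targets (7 and 25 of 38), the 3 study genes (0 and 2), NRF2 targets (8 and 6 of 17), the unfolded protein response (6 and 9 of 18), integrated stress response targets (6 and 14 of 25, median -0.15, camera direction up), granule and progenitor genes (3 and 2 of 9, median -0.04, mean 0.18, camera direction down) and ribosomal proteins (5 and 15 of 39). With upper-quartile factors the medians of the last 3 turned to 0.02, 0.13 and 0.06. Adjusted over the list alone, only mitosis genes (2 and 28) and ribosomal proteins (5 and 14) had other counts. Between the compounds CD3D, a subunit of the T cell receptor, was higher with FB23-2 by 2.68 ± 0.18.

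Most genes called with FB23 moved the same way with FB23-2, and further. CDKN1A, GDF15, INSIG1 and SLC19A1 were examples: GDF15 rose by log2 0.97 with FB23 and 4.19 with FB23-2, and INSIG1 by 0.98 and 3.14. Of the 3144 genes called with FB23, 2590 (82.4%) were called in the same direction with FB23-2, 1341 up and 1249 down, where independent lists would share 681 and 618. Another 302 were called in opposite directions, 157 of them up and 145 down with FB23, and 252 were not called with FB23-2. Among the 2590 the change was larger with FB23-2 for 2257 and smaller for 26 by the test between the compounds. Over 11293 genes called with at least 1 compound, the total least squares slope of FB23-2 on FB23 fold changes was 7.01 (jackknife SE 1.69). Such a slope follows the direction of greatest joint spread, so genes changed by FB23-2 alone steepen it. It is therefore not the ratio of the 2 effects for a typical shared gene. Both comparisons share the DMSO libraries: 20 simulations of unchanged groups against these controls gave a correlation across genes of 0.531, against 0.531 observed, and a covariance of 0.0115 against 0.267 observed, a difference of 0.256. The observed correlation was no higher than in unchanged groups, so it does not by itself show a shared response. The same-sign overlap was 0 in every simulation, against 2590 observed. The simulated groups held no changed genes, so few calls could arise and an overlap near 0 was to be expected. That result shows only that spread of the simulated size gives no such overlap, and it does not tell where the 2590 came from. The difference in covariance already leaves out the simulated share. Genes are not independent replicates, and the 3 controls cannot be split, so a control shift beyond the simulated spread cannot be excluded.

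**Figure D4:**
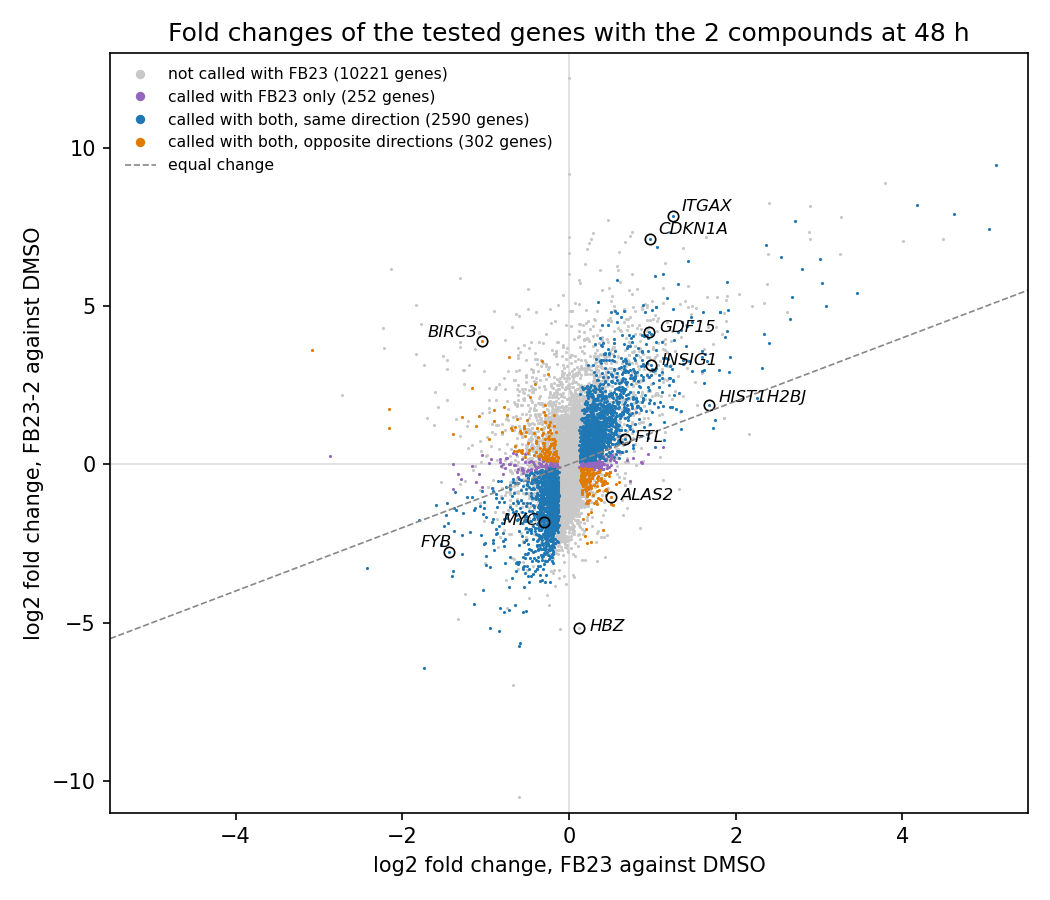
Log2 fold change with FB23 (horizontal) and with FB23-2 (vertical) of the 13365 tested genes, 1 point per gene, with 11 genes named and a dashed line for equal change. The 2590 genes called in the same direction mostly lie farther from 0 on the FB23-2 axis, and 302 genes lie in opposite quadrants.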

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

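In this part, thinning, scaling by library totals and removal of GC and length trends were chosen only after the data were seen, while the other tests were planned.

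Genes called in opposite directions by FB23 and FB23-2, and called between the compounds by edgeR, numbered 302. Of the genes named from the lists, 10 were of this kind, and each is given by its log2 fold change of FB23-2 against FB23. ALAS2, a haem synthesis enzyme, stood at -1.54, having risen by 0.51 with FB23 and fallen by 1.04 with FB23-2. KRT19, an intermediate filament gene, stood at 2.96, from -0.41 and 2.55. PFKFB4, a regulator of glycolysis, stood at 1.94, from -0.30 and 1.64. SRXN1, an antioxidant enzyme, stood at -1.45, from 0.23 and -1.22. The calls of ALAS2, KRT19 and PFKFB4 with FB23 held in all 20 other settings, as did that of SRXN1 with FB23-2, while the call of SRXN1 with FB23 was not tested in other settings.

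For the other 6 the call with FB23 was lost under some alternative, so the opposite direction is less certain than the difference between the compounds. SLC16A3, a lactate transporter, stood at 3.56, and its fall with FB23 was lost without FB23 replicate 3 (log2 fold change -0.87, edgeR adjusted p = 0.0553) and after thinning (-0.98, 0.0618). BIRC3, an inhibitor of apoptosis, stood at 4.96, and its fall of -1.05 with FB23 was lost without DMSO replicate 1 (-1.16, adjusted p = 0.0503), 2 (-1.08, 0.0758) or 3 (-0.91, 0.128) and without FB23 replicate 2 (-0.93, 0.114) or 3 (-0.80, 0.141), with the replicate block (-1.01, 0.058), with only the 6 libraries compared (-1.03, 0.0691) and after thinning (-0.37, 0.565), by edgeR, and with limma-voom (-1.09, 0.05). LYZ, the lysozyme gene, stood at 1.69, and its fall with FB23 was lost without DMSO replicate 2 (-0.49, adjusted p = 0.0976) or 3 (-0.52, 0.0702) and without FB23 replicate 1 (-0.44, 0.0575) and after thinning (-0.50, 0.112), by edgeR. ICAM1, an adhesion receptor, stood at 3.12, and its fall with FB23 was lost without DMSO replicate 1 (-0.20, adjusted p = 0.12) or 2 (-0.25, 0.0575) and without FB23 replicate 2 (-0.23, 0.0767), by edgeR. AURKB, a mitotic kinase, stood at -0.34, and its rise with FB23 was lost without DMSO replicate 1 (0.17, adjusted p = 0.119) or 2 (0.18, 0.106) and without FB23 replicate 3 (0.14, 0.131), with the replicate block (0.19, 0.061) and after thinning (0.15, 0.147), by edgeR, and with the DESeq2 Wald test (0.18, 0.065). HBA2, an adult globin gene that shares reads with HBA1, stood at -2.47, and its rise with FB23 was lost with the DESeq2 Wald test (0.39, adjusted p = 0.0521).

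FB23-2 changed more genes than FB23, 3.51 times as many. A difference in depth as the whole cause is argued against by thinning all libraries to 1 total, after which the ratio was 4.23. Under 3 other scalings the lowest ratio was 3.49, so the ratio did not hang on the choice among them. Each sets 1 factor per library, however, so they cannot tell whether a shift common to most genes was scaled away. The lowest ratio under any alternative was 2.48, with GC and length trends removed. A difference in dose, which the labels do not give, and a difference between the compounds themselves remain open and were not tested.

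Regrouping the 6 libraries of each comparison gave 10 splits. As many genes as the real value were called in 1 split, the real one, for FB23 against DMSO (3144, highest other 1), in 1 split for FB23-2 against DMSO (11041, highest other 0) and in 1 split for FB23-2 against FB23 (10890, highest other 0). With 10 splits no share under 0.05 can be reached.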

How the results depend on the processing

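Scaling by library totals, thinning and the removal of GC and length trends were added after the data were seen, and the other alternatives were planned. Under these, the named genes were called or not called as before in 6680 cases, lost the call in 143, gained it in 4 and reversed in 1. Among genes not called the sign could turn, as for HLA-C with FB23 (-0.0041, and 0.0174 with library totals). Lists kept the result in 822 cases, lost it in 27 and gained it in 15, and counts and the slope were taken as the same in 133 cases and as moved in 7. The band for counts was wide: without DMSO replicate 1, 2096 genes called with FB23, against 3144, were scored as the same. The band for the slope was its jackknife SE, which comes from the same fits that leave out 1 library. These scores therefore do not show that counts or the slope were stable. Of the gains of lists 13 were with fry, which tests a list against no change and not against other genes. By fry 8 lists were called for FB23 against DMSO, 23 for FB23-2 against DMSO and 21 for FB23-2 against FB23. Most losses of single genes were in FB23 against DMSO, and most losses of lists were in the comparisons of FB23-2. With an added minimum of 1 on the absolute log2 fold change, the calls were 155 for FB23 against DMSO, 4913 for FB23-2 against DMSO, 4300 for FB23-2 against FB23 and 131 for genes changed the same way by both compounds, because fewer genes meet both limits. Without the filter on low counts the slope was 5.27, the cause of which was not tested, and 66.1% of calls with FB23 were higher, against 52.4% with the filter. With an estimated correlation 6 lists were called for FB23-2 against DMSO and 6 for FB23-2 against FB23, the cause of which was not tested. RPL5 between the compounds went from -0.41 to 0.08 when GC and length trends were removed (log2 fold change 0.0755, edgeR adjusted p = 0.0259, and between 2.3e-17 and 0.0259 over its alternatives), the cause of which was not tested. Leaving out 1 library in turn gave 2096 to 3303 genes for FB23 against DMSO (1133 to 1719 higher and 963 to 1584 lower), 10740 to 11293 for FB23-2 against DMSO, 10556 to 10980 for FB23-2 against FB23, 1737 to 2694 changed the same way by both, a slope of 5.70 to 7.53, and 6 to 8, 15 to 16 and 17 to 17 lists. With the replicate block the counts were 2504, 10883 and 10705 genes, an overlap of 2091, a slope of 6.999 and 7, 16 and 17 lists. Deviations of libraries with the same number correlated between -0.185 and 0.0856, and those with different numbers between -0.135 and 0.166. Between DMSO and FB23 each library correlated best with its own number, at 0.0439, 0.0755 and 0.0589. Between DMSO and FB23-2 most did, but DMSO replicate 2 had 0.0257 with its own number and 0.0403 with FB23-2 replicate 3. Between FB23 and FB23-2 no library did. No pairing by number held across all groups and the values were small, but with 3 libraries per group a weak one cannot be excluded, above all between DMSO and FB23.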

Other observations

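The genes in the first paragraphs and the tests of the cell type and of S phase were chosen only after the values had been seen, and the test of RNA without a poly(A) tail was planned before its result.

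The genes in this paragraph and the next are single genes chosen after their values were seen and do not stand for gene classes. KLF2, a transcription factor, stood at 0.981 CPM in DMSO, 2.02 with FB23 and 115 with FB23-2 (log2 fold changes 1.05 ± 0.21 and 6.88 ± 0.11, SE, 3 libraries per group). The immediate-early gene FOS rose by 1.04 ± 0.17 and 3.87 ± 0.15, JUN by 0.78 ± 0.06 and 2.75 ± 0.06 and EGR1 by 0.77 ± 0.06 and 2.12 ± 0.06. The transferrin receptor gene TFRC fell by 0.35 ± 0.05 and 1.18 ± 0.05, and the ferritin genes FTH1 and FTL rose by 0.47 ± 0.04 and 0.67 ± 0.05 with FB23 and by 0.68 ± 0.04 and 0.80 ± 0.05 with FB23-2. LIN28B, an RNA-binding protein of fetal cells, went from 170 CPM in DMSO to 141 with FB23 and 15.0 with FB23-2.

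With FB23-2, the transcription factor GATA2 rose by 0.45, GATA1 fell by 1.13 ± 0.05, NFE2 by 1.65, GFI1B by 1.26, TAL1 by 0.51 and LMO2 by 2.69 ± 0.08. The haem enzymes UROD and FECH fell by 1.63 and 1.01. With FB23, LMO2 fell by 0.90 ± 0.07 and GFI1B by 0.28, whereas GATA1, GATA2, NFE2, TAL1, UROD and FECH were not called by edgeR, though GATA1 and UROD were called with GC and length trends removed (adjusted p = 0.00923 and 0.0197). With FB23-2 B2M, the light chain of HLA class I, rose by 0.94 ± 0.05, HLA-C by 1.44 ± 0.07 and HLA-E by 2.13 ± 0.06, while TAP1 was at 0.00 with FB23-2 and at -0.33 with FB23, a call lost without DMSO replicate 1 (-0.29, edgeR adjusted p = 0.106) and in 5 other settings.

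All 9 libraries labelled NB4 combined high globin transcripts with granule genes near 0. Erythroid cells mixed into promyelocytic cells would bring granule transcripts along, but the highest TPM of MPO, ELANE, PRTN3, AZU1 and CTSG in any library was 1.77, which argues against a mixture. A candidate explanation is cells of another line than the label, such as K562, a leukaemia line with globin expression that has lost MTAP, CDKN2A and CDKN2B on chromosome 9. The highest TPM of these 3 genes in any library was 0.21, with 10 of 192662531 counts over the 9 libraries. RPS6, which ends at 19380254, and CAAP1, which starts at 26840685, had medians of 3856 and 6.89 TPM. Between them MLLT3 had a median of 3.39 TPM, but genes nearer the 3 were also near 0, such as HACD4 with 1 count, KLHL9 with 6 and TUSC1 with 1. The values therefore do not show where a loss would end. Other lines may share this loss, and NB4 cells were not compared here.

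Replication-dependent histone genes were higher with FB23 (median 1.13), and more cells in S phase would raise the E2F and DNA replication list as well, but its median was -0.0117 and its highest called member, RRM2, rose by 0.47, which argues against S phase as the whole cause. Carry-over of RNA without a poly(A) tail cannot be told apart: the median of other such RNAs was -0.13, but only 2 could be tested, and with FB23-2 it was 1.47, with RN7SK called higher by 2.39 ± 0.47 (edgeR adjusted p = 0.000158). RN7SL2, left out because its value had been seen, rose by 1.75 with FB23. Its near-identical copy RN7SL1, 1 of the 2 tested, was not called (0.15 ± 0.40, edgeR adjusted p = 0.833). The 2 may share reads, so the rise of RN7SL2 is uncertain. Summed over the 39 listed RNAs, which do not include RN7SL2, levels were 1.82 ± 0.182 CPM (SD, n = 3) in DMSO, 1.87 ± 0.986 with FB23 and 4.46 ± 1.203 with FB23-2, against 84.7 ± 1.42, 185 ± 6.25 and 783 ± 12.6 CPM for the histone list. Most of each histone sum came from 1 gene, HIST1H1C, at 53.9, 122 and 475 CPM. An effect of the compounds on histone transcripts remains open and was not tested.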
